A study of Mus musculus with 12 samples.

How the data were processed

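Polyadenylated RNA from sorted splenic B cells, CD4 T cells and CD8 T cells of C57BL/6 mice was sequenced with paired ends, per the labels, in 6 groups of 2 animals each (3 cell types, WT and cTKO). Each sample came from a sort of 500000 cells, per the labels. The only table analysed here is the authors' comparison of cTKO with WT in CD8 T cells. The 4 samples behind it were 1 female and 1 male per genotype, per the labels, and p-values of single genes measure the spread between these animals. The p-values of gene lists by cameraPR, of windows, of chromosomes and of permutations cover genes, not animals. Tables of values for B cells and CD4 T cells were not analysed here.

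STAR and DESeq2 were used, per the submitters' processing notes, and the builds named there are mm10 and GRCm38.p6. The annotation, the counting tool, strand handling and all versions are not given in the sources used here. The mean normalized count of each gene over all 4 libraries is a signal that the authors made from read counts divided by size factors, per the file headers. The log2 fold change and its standard error, also on the log2 scale, are those the authors deposited. The test score deposited by the authors equalled the fold change over its standard error in every row (largest difference 2.17e-08). The p-value and the adjusted p-value of each gene are as the authors deposited them. No adjusted p was given for 5181 genes with a p-value, all with a mean of 3.43 or less, while genes with one had a mean of at least 3.45. The file headers do not state the direction of the fold change, which was read as cTKO over WT because Hist1h1c, Hist1h1d and Hist1h1e are negative. An inverted reading would turn every direction in the text.

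The calls of single genes are those of the authors' test, a choice fixed before the data were examined for tables without sample columns. A fit by limma on recovered reads was added as an alternative after the data were seen. Genes were called higher or lower at the authors' adjusted p under 0.05. Positions are those of NCBI RefSeq genes on GRCm38.p6, matched by Entrez identifier for 24383 of 24421 genes. Some symbols in the table have been turned into dates by a spreadsheet and were not named.

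Whole reads per library were worked back from the mean normalized counts. The mean of a gene is a sum of 4 whole numbers, each multiplied by what 1 read of a library is worth. The 4 lowest means in the table are the worth of 1 read in each library, and the sign of the fold change at each of them gives its side: 102 genes had a single read in the larger WT library alone, 97 in the smaller WT, 1165 in the larger cTKO and 156 in the smaller cTKO library. Size factors from these steps were 1.214423 and 0.866028 for WT and 1.207396 and 0.804969 for cTKO. For means below 15, each of 2305 distinct values had exactly 1 solution in whole numbers. From a mean of 20 to 1000, solutions were kept where a 2-group negative binomial fit, at the dispersion that gives the deposited standard error, returned the deposited fold change within 2e-05 (2e-06 from a mean of 100, with 2e-05 tried again below 500). Where a genotype had 0 reads, or at low means where no solution met this limit, the mean alone decided. This gave 1 solution for 14140 of 14173 genes (99.8%). From a mean of 20 the median fold change error was 6.31e-07 on the log2 scale and the largest 0.000101. Means of 1000 and more were not solved, so reads per library are missing for 3978 genes. Y-linked genes and Xist were solved at any mean, with a looser limit on the fold change. Their search allowed any number of reads in 1 library of each genotype and only few in the other. The recovery gives the genotype of a library and not its animal. In simulated reads of the same genes, 6791 of 6791 genes with a mean under 20, 1780 of 1781 with a mean of 20 to 100 and 5103 of 5114 with a mean of 100 to 1000 had 1 solution, and each of these was right. A fold against a genotype with 0 reads is a lower bound against 3 reads over that genotype's libraries. Floors and intervals from reads cover counting error only.

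Xist and the Y-linked genes were used to match the libraries with the sexes in the labels. The search allowed many reads in only 1 library per genotype, so that form was set in advance and is no check of the labels. Which library of each genotype held the reads was left to the search, and each gene had 1 solution. Ddx3y had 1904 and 1652 reads in the smaller WT and the smaller cTKO library and 0 in both larger ones, and most Xist reads lay in the larger ones. The larger library of each genotype therefore goes with the female and the smaller with the male animal, so size and sex of the libraries cannot be told apart.

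A total of 26 gene lists were fixed before the data were examined. Of these, 24 were tested with cameraPR of limma (version 3.58.1, R 4.3.3) on the authors' test score, two-sided, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the lists. None of the 15 mitochondrially encoded genes is in the table, and the sex-linked list was not tested. Estimated correlations came from camera on log2 normalized recovered reads with 1 added. The same scale was used for limma with an intensity trend on 8961 genes, which was chosen after the data were seen. On simulated reads of these genes limma called 5 of 100 genes changed 2-fold and 70 of 100 changed 4-fold, none in the wrong direction, and 1 unchanged gene. In 20 further draws it called 3 to 27 (median 9) and 46 to 88 (median 72) of these, none in the wrong direction, and 0 to 5 unchanged genes. On simulated scores of 12972 genes, drawn independently of each other, cameraPR called both shifted lists, and any list in 2 of 200 simulations with no shift. This does not give the rate of false calls for lists whose members move together. Estimated correlations lay between -0.40 and 0.81 over the lists.

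Named genes follow a rule fixed before the data were examined: Hist1h1c, Hist1h1d and Hist1h1e first; the 12 higher and 12 lower genes with the smallest p-values among those past the threshold with a mean of at least 50 and a named symbol; and per list up to 4 members past the threshold with the smallest p-values, or the 2 with the highest means where none passed. The rule gave 95 genes, of which a few are left out of the text. Members named beyond it, such as H1fx, Hist1h1b, Prf1, Fcgr2b, Fcer1g, Ncr1, Cd69, Cd79a, S100a8, Tgfb1, Sesn1, Pkm and Ifi204, were chosen after their values were seen, as were genes named by chromosome in the closing section. Alternatives were other thresholds, filters on the mean, gene sets, centring, ranking statistics, correlations and a rank-based list test. Analyses used Python 3.11.15 with numpy, pandas, scipy, numba and matplotlib.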

Results

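The series asks what loss of linker histone H1 does to gene expression in lymphocytes. Linker histone H1 binds the nucleosome and the DNA that enters and leaves it, and helps to compact chromatin. B cells, CD4 T cells and CD8 T cells were sorted from mouse spleen by flow cytometry, and polyadenylated RNA was sequenced from wild-type (WT) animals and from animals with a triple H1 knockout (cTKO). The labels describe 12 samples in 6 groups of 2 animals. A table was used here for the CD8 T cells alone, so the comparison is of 2 WT animals (1 female, 1 male) with 2 cTKO animals (1 female, 1 male). That table holds the authors' own comparison of 24421 genes, of which 18153 had a read in at least 1 library and 12972 carried an adjusted p-value. The mean normalized counts of all genes sum to 16257610. Whole reads per library could be worked back from these means for 14140 of the 14173 genes with a mean above 0 and below 1000, and gave 2 libraries on each side, with size factors of 1.21 and 0.866 for WT and 1.21 and 0.805 for cTKO. They are called the larger and the smaller library of each genotype, and reads are given in that order.

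Reads of the deleted H1 genes were found in WT libraries and in neither cTKO library. Hist1h1c (Entrez 50708, chromosome 13, 23738807 to 23739531, GRCm38) had 41 reads in the larger and 56 in the smaller WT library and 0 in both cTKO libraries, at least 31.3-fold lower against a floor of 3 reads over the group. Hist1h1e (Entrez 50709, chromosome 13, 23621777 to 23622558) had 64 and 112 reads in WT and 0 in both cTKO libraries, at least 56.7-fold lower. Hist1h1d (Entrez 14957, chromosome 13, 23555032 to 23555807) had 5 and 11 reads in WT and 0 in both cTKO libraries. In the authors' deposited table the adjusted p was 6.03e-05 for Hist1h1c, 1.36e-06 for Hist1h1e and 0.128 for Hist1h1d. The table does not state which genotype is the numerator, and the fold changes were read as cTKO over WT because these 3 genes are negative, so they cannot serve as a separate check of the labels. Most replication-dependent histone mRNAs lack a poly(A) tail, and polyadenylated RNA therefore holds only part of their transcripts.

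Other linker histone genes were higher or did not pass. H1f0, which codes for a replication-independent H1, rose 88.8-fold in the authors' deposited table (log2 fold change 6.47, SE 0.32, adjusted p 4.71e-88), the smallest p-value among named genes that were higher. Hist1h1a rose as well in the authors' deposited table (log2 fold change 3.85, SE 1.17, adjusted p 0.0115), from 4 and 1 reads in WT to 37 and 29 in cTKO. H1fx had 0 reads in both WT libraries and 16 in each cTKO library, at least 11.0-fold higher. Hist1h1b did not pass, with a log2 fold change of 1.23 in the authors' deposited table. Of 7 tested H1 genes 3 were higher and 2 lower, and adjusted over the list alone 4 were higher and 3 lower. The list, which holds the 3 deleted genes, was called higher (adjusted p 0.0275, cameraPR), with a median log2 fold change of 1.23 and a mean of -0.63. Over the 6 members with recovered reads, which lack H1f0, the direction was lower and did not pass (adjusted p = 0.707 with an estimated correlation and 0.344 with the preset one), so the list has no shared direction.

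In the authors' deposited table, 1268 genes were higher and 468 lower in cTKO CD8 T cells at an adjusted p under 0.05, so 73.0% of the 1736 changed genes were higher. At least 2-fold differences were found in the authors' deposited table for 1219 of the higher and 368 of the lower genes, and the median log2 fold change was 2.34 among higher and -1.27 among lower genes. Reads could be recovered for 1020 of the higher genes, and in 1018 of these both cTKO libraries lay above both WT libraries. Both cTKO libraries lay below both WT libraries in 258 of 260 lower genes with recovered reads. Among all recovered tested genes with a mean of at least 10, the groups were apart in these ways in 35.3% and 24.4%. The larger cTKO library held over 2 times the normalized reads of the smaller in 339 of the 1020, and the reverse was seen in 30. The share of higher genes differed with the level of expression: 92.4% of the 343 changed genes with a mean of 10 to 50 were higher, against 50.5% of the 210 with a mean of at least 2000. All tested genes shifted in the same way, changed or not, with a median log2 fold change of 0.86 and -0.24 at these levels. The difference in shares is therefore not particular to the changed genes. The median log2 fold change of genes with a mean of at least 100 was -0.10 in the authors' deposited table, and re-centring on it moved every fold change up by that amount.

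**Figure D1:**
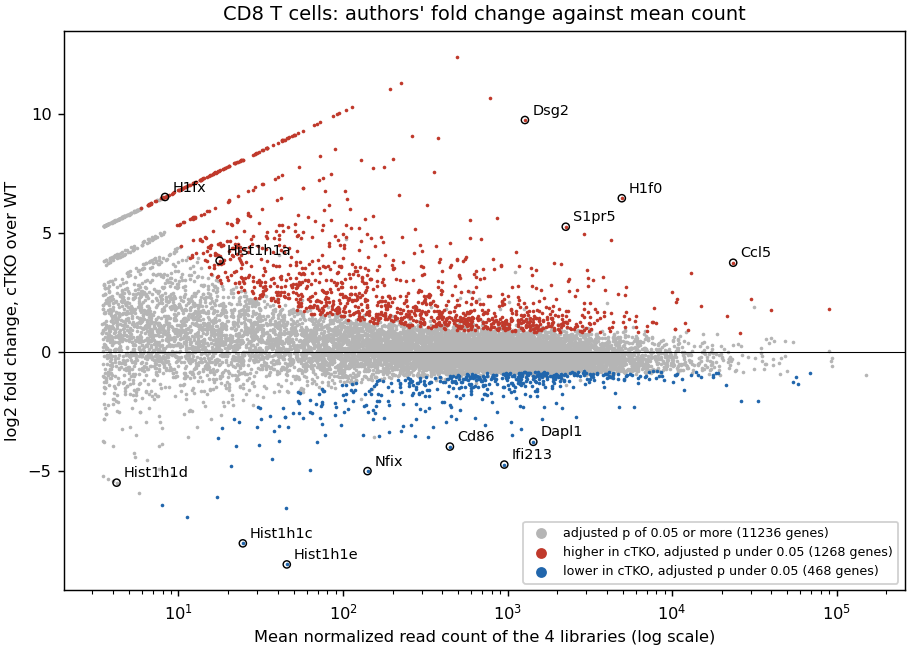
log2 fold change of cTKO over WT (vertical axis) against the mean normalized read count of the 4 libraries (horizontal axis, log scale) for the 12972 genes with an adjusted p in the authors' deposited table; red points are the 1268 higher and blue points the 468 lower genes, and 13 genes are named. The straight lines of points at the upper left are genes with few or no WT reads, whose fitted fold changes have no lower group to rest on.

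The 12 named genes with the smallest p-values among higher genes were led by H1f0 and by S1pr5, a sphingosine 1-phosphate receptor that governs the exit of natural killer and effector T cells from tissue. S1pr5 rose 38.7-fold (log2 fold change 5.27, SE 0.32, adjusted p 4.99e-57) in the authors' deposited table, Cd163l1, a scavenger receptor, 26.4-fold and Kcnj8, a potassium channel subunit, 18.5-fold. The adhesion gene Dsg2, a desmosomal cadherin, had the steepest change of these 12 in the authors' deposited table, with a log2 fold change of 9.76 (SE 0.72, adjusted p 2.47e-38). Ccl5, a chemokine that memory and effector CD8 T cells store and release, rose 13.5-fold in the authors' deposited table (log2 fold change 3.76, SE 0.30, adjusted p 5.48e-34). Ttn rose from 24 and 26 reads in WT to 1885 and 609 in cTKO, and Serpina3f, a serine protease inhibitor, from 42 and 32 to 957 and 746. Serpina3g, its neighbour on chromosome 12, Lrrk1, a kinase, and the aquaglyceroporin Aqp9 rose 10.9-fold, 13.4-fold and 13.1-fold in the authors' deposited table. Rps4l, a ribosomal protein S4 copy, went from 25 and 42 reads to 1188 and 1925. Counts of Rps4l and of the Serpina3 genes are uncertain where reads are shared with near-identical family members, and a strain difference between the animals near Rps4l was not tested.

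Ifi213, a member of the interferon-inducible Ifi200 family on chromosome 1, led the lower genes. Its reads fell from 2452 and 1441 in WT to 106 and 40 in cTKO (log2 fold change -4.73, SE 0.37, adjusted p 3.26e-34 in the authors' deposited table), and Mndal of the same family fell by 2.81 on the log2 scale in the authors' deposited table. A strain difference between WT and cTKO animals near these genes was not tested. Cd86, a costimulatory ligand best known on antigen-presenting cells, went from 1321 and 510 reads to 55 and 50. Gsn, which severs actin filaments, went from 1711 and 1038 reads to 184 and 129, and Cnn3, an actin-binding calponin, fell by 3.48 on the log2 scale in the authors' deposited table. Mapk11, the p38 beta kinase, went from 698 and 370 reads to 46 and 40. Nfix, a transcription factor, had 348 and 224 reads in WT and 4 and 12 in cTKO (32.0-fold lower, adjusted p 2.58e-14 in the authors' deposited table). Itga6, the laminin-binding integrin alpha 6, went from 1825 and 1231 reads to 313 and 200. The remaining genes of the 12 were Egr2, an early response transcription factor, Cd79b, a B cell receptor subunit, the receptor Gpr34 and the channel Trpm1. Their log2 fold changes in the authors' deposited table were -2.94, -2.76, -3.14 and -3.37.

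**Figure D2:**
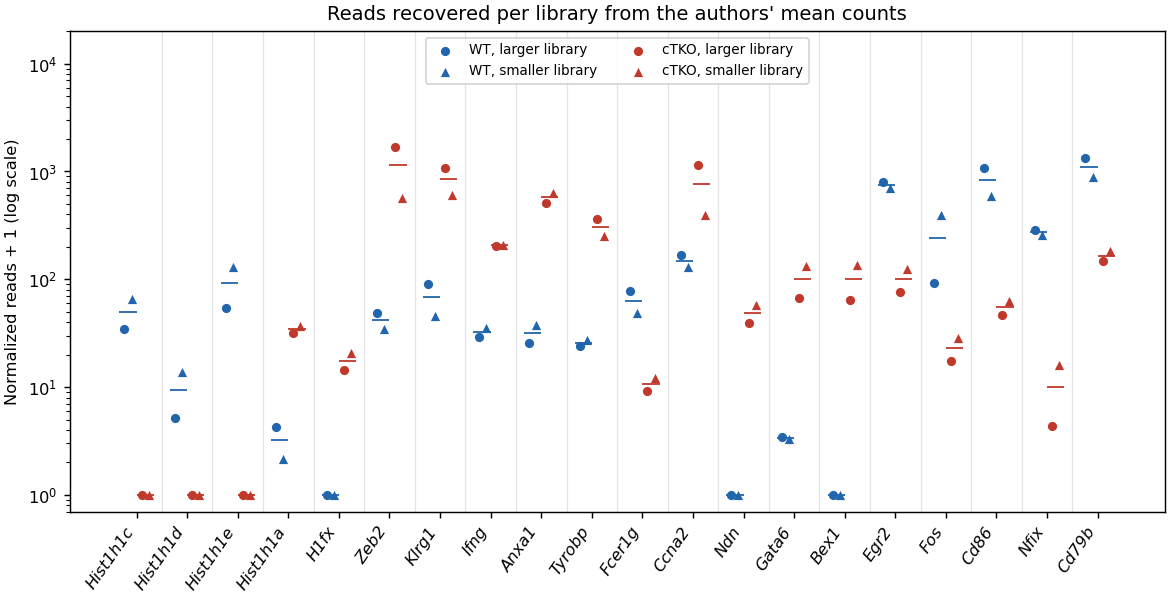
Normalized reads plus 1 (log scale) recovered for 20 genes in each of the 4 libraries; blue marks WT and red cTKO, circles the larger and triangles the smaller library of each genotype, and bars the mean of 2 libraries. Hist1h1c, Hist1h1d and Hist1h1e sit at 0 reads in cTKO, and H1fx, Ndn and Bex1 at 0 reads in WT.

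Genes of effector and memory CD8 T cells made up the broadest shift among the fixed lists. Of 24 tested effector and cytotoxic genes, 18 rose and 0 fell in the authors' deposited table, with 20 higher when adjusted over the list alone, and the median log2 fold change was 2.66. S1pr5 and Ccl5 led this list, followed by Klrc1, which codes for the inhibitory receptor subunit NKG2A and rose 8.83-fold in the authors' deposited table, and Zeb2, a transcription factor of terminal effector cells. Zeb2 had 58 and 29 reads in WT and 2055 and 459 in cTKO (log2 fold change 4.80, SE 0.49, adjusted p 3.12e-20 in the authors' deposited table). The other 6 members did not pass, among them the pore-forming protein gene Prf1 with a log2 fold change of -0.24 in the authors' deposited table. The list as a set was higher by cameraPR (adjusted p 1.62e-39); over its 10 members with recovered reads, adjusted p = 0.707 with an estimated correlation and 1.08e-05 with the preset one.

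Of 19 memory and virtual memory genes, 16 rose and 1 fell, the same numbers when adjusted over the list alone, and the list was called higher (adjusted p 6.30e-26, cameraPR; adjusted p = 0.707 with an estimated correlation over 4 members). Cd38, an NAD-cleaving surface enzyme, and Ahnak, a very large scaffold protein gene, rose 12.2-fold and 10.1-fold in the authors' deposited table. Anxa1, a phospholipid-binding protein gene, had 30 and 32 reads in WT and 619 and 513 in cTKO. The single lower member was Fcgr2b, an inhibitory Fc receptor, with a log2 fold change of -4.78 in the authors' deposited table.

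Markers of natural killer cells moved with these lists, although the cells were sorted as CD8 T cells. Their list was fixed for natural killer and gamma delta T cells, with 20 genes, of which 15 were found in the authors' deposited table. The gamma delta T cell receptor genes were not among those found, and Sox13 and Zbtb16 were not tested. The list therefore says nothing of gamma delta T cells. Of 13 tested markers, 8 rose and 1 fell, again the same numbers when adjusted over the list alone, and the list was called higher (adjusted p 3.39e-10, cameraPR; adjusted p = 0.707 with an estimated correlation over 11 members). Klrb1c, which codes for the NK1.1 antigen, went from 180 and 119 reads to 1606 and 881, and Klra3, a Ly49 receptor gene, from 111 and 88 to 926 and 850. Tyrobp, the adaptor DAP12, went from 28 and 23 reads to 440 and 201, and Gzma, a granule protease also in the effector list, rose 10.9-fold in the authors' deposited table. Fcer1g, another signalling adaptor of natural killer cells, was the lower member, with 94 and 41 reads in WT and 10 and 9 in cTKO. Ncr1, which codes for NKp46, did not pass and had 2 and 4 reads in WT and 22 and 1 in cTKO. Reads of the Ly49 genes are uncertain, since these genes form a family of near-identical copies.

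T cell identity genes gave no such shift. Among 18 tested members only Lat, an adaptor of T cell receptor signalling, passed, and it fell by 1.19 on the log2 scale in the authors' deposited table. The list did not pass (adjusted p 0.125, cameraPR). Naive T cell genes were lower as a list (adjusted p 0.00596, cameraPR; adjusted p = 0.722 with an estimated correlation over 3 members), with 3 of 20 members lower and 0 higher, and 7 lower and 1 higher when adjusted over the list alone. These 3 were the chemokine receptors Ccr9 and Ccr7 and the naive cell gene Dapl1, with log2 fold changes of -1.86 (SE 0.41), -0.95 (SE 0.32) and -3.77 (SE 1.17) in the authors' deposited table. The call of Ccr7 was lost when fold changes were re-centred.

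Lists of genes induced through the T cell receptor and by handling of the cells were called lower, although many members did not pass. In the T cell receptor activation list 1 of 18 members rose and 4 fell, as when adjusted over the list alone (adjusted p of the list 0.00539, cameraPR; adjusted p = 0.707 with an estimated correlation over 11 members). Egr2 went from 972 and 609 reads to 90 and 99, and Nr4a1, an orphan nuclear receptor induced by receptor signalling, from 859 and 511 to 162 and 140. Egr1 fell by 2.32 on the log2 scale in the authors' deposited table, and Cd69, an early activation antigen, fell by 0.97. The chemokine gene Xcl1 was the member that rose, from 236 and 318 reads to 735 and 927. In the dissociation stress list, which also holds Egr1, 9 of 18 members fell and 1 rose (12 lower and 1 higher adjusted over the list alone), and the list was lower (adjusted p 6.43e-06, cameraPR; adjusted p = 0.707 with an estimated correlation over 7 members). Dusp1 went from 734 and 631 reads to 172 and 139. Several members differed between the WT libraries: Fos had 110 and 341 reads in WT and 20 and 22 in cTKO, Jun 226 and 547 against 228 and 84, and Hspa1b 170 and 597 against 76 and 27. On recovered reads the list was called without the larger WT library only, and not without the smaller WT, the larger cTKO or the smaller cTKO library (adjusted p 0.368, 0.495 and 0.652, cameraPR). Ier3, the member that rose, went from 50 and 123 reads to 764 and 623.

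B cell markers were lower as a list (adjusted p 0.00133, cameraPR; adjusted p = 0.707 with an estimated correlation over 13 members). The 4 lower of 13 tested markers, the same number when adjusted over the list alone, were Cd79b and 3 genes of antigen presentation by MHC class II. Cd79b went from 1612 and 762 reads to 176 and 145, H2-Ab1 from 333 and 298 to 72 and 25, H2-Aa from 133 and 173 to 41 and 12, and Cd74 from 502 and 479 to 252 and 92. Cd79a did not pass, with 47 and 67 reads in WT and 44 and 25 in cTKO. Of 16 myeloid and dendritic markers, 2 rose, and 3 were higher and 1 lower when adjusted over the list alone (adjusted p of the list 0.0672, cameraPR). They were the integrin genes Itgax, from 56 and 44 reads to 2429 and 509, and Itgam, from 34 and 30 to 434 and 138. The neutrophil gene S100a8 had 22 reads in the larger cTKO library and 0 in the other 3 libraries. Among 9 CD4 T cell and regulatory T cell markers, Zbtb7b (15 and 11 reads against 110 and 34) and Gata3 rose, and the list did not pass (adjusted p 0.875, cameraPR). Gata3 rose by 0.84 on the log2 scale in the authors' deposited table, and its call was lost with no filter on the mean. Among 6 erythroid and platelet markers Car2 fell, from 215 and 142 reads to 96 and 48, and the list did not pass (adjusted p 0.405, cameraPR). The call of Car2 was lost with no filter and with re-centring.

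Cell cycle genes were higher as a list (adjusted p 0.00221, cameraPR; adjusted p = 0.722 with an estimated correlation over 21 members), and much of the difference lay in the larger cTKO library. Of 30 members 9 rose and 0 fell, as when adjusted over the list alone. Ccna2, which codes for cyclin A2, had 202 and 111 reads in WT and 1383 and 315 in cTKO, Top2a, a DNA topoisomerase, 561 and 249 against 2760 and 604, Nusap1, a spindle protein gene, 266 and 136 against 1005 and 356, and Cenpf, of the kinetochore, 87 and 51 against 527 and 120. Core histone genes, by contrast, gave 1 higher member of 29, Hist1h4d, with 56 and 70 reads in WT and 428 and 161 in cTKO, and no call for the list (adjusted p 0.405, cameraPR).

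**Figure D3:**
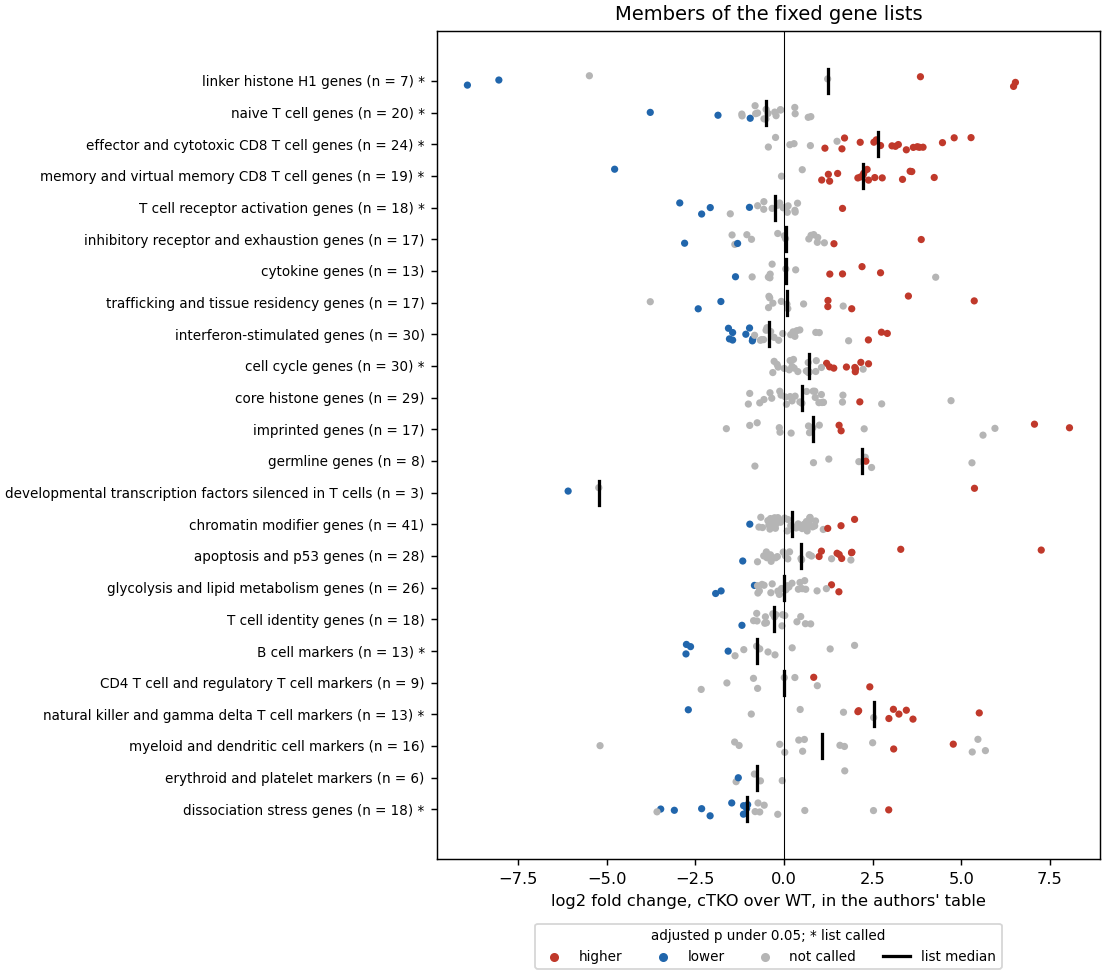
log2 fold change of cTKO over WT in the authors' deposited table (horizontal axis) for the tested members of 24 fixed gene lists (rows, with the number of tested members); red points are higher and blue points lower genes at an adjusted p under 0.05, grey points are neither, black bars are list medians, and asterisks mark the 9 lists called by cameraPR. The medians of the effector, memory and natural killer lists lie at 2.66, 2.23 and 2.53.

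The other lists did not pass as sets, and their changed members went both ways in most of them. Among 28 apoptosis and p53 genes 9 rose and 1, Sesn1, fell (10 and 1 adjusted over the list alone; adjusted p of the list 0.112, cameraPR). Bcl2l11, which codes for the death-promoting protein BIM, rose 3.74-fold in the authors' deposited table, Pmaip1, which codes for NOXA, went from 186 and 121 reads to 572 and 347, and Cdkn1a, a cell cycle inhibitor gene, from 16 and 3 to 100 and 69. Eda2r, a receptor gene induced by p53, had 0 reads in both WT libraries and 36 and 20 in cTKO, at least 19.3-fold higher. Among 13 cytokine genes 4 rose and 1 fell (4 and 2 adjusted over the list alone; adjusted p of the list 0.405, cameraPR). Ifng went from 34 and 30 reads to 245 and 168 and Tnfsf10, which codes for the death ligand TRAIL, from 164 and 188 to 1355 and 395. Xcl1, Tgfb1 and Ltb were the other changed members, and Ltb fell by 1.37 on the log2 scale in the authors' deposited table. Among 17 inhibitory receptor and exhaustion genes, 2 rose and 2 fell, as when adjusted over the list alone (adjusted p of the list 0.796, cameraPR). Entpd1, which codes for the ectonucleotidase CD39, went from 80 and 52 reads to 1081 and 764 and Cd160 rose 2.66-fold in the authors' deposited table. Cd200 went from 380 and 189 reads to 36 and 38, and Tox, a transcription factor of exhausted T cells, fell by 1.31 on the log2 scale in the authors' deposited table.

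Genes of trafficking and tissue residency split in the same way, with 5 of 17 higher and 2 lower, as when adjusted over the list alone (adjusted p of the list 0.773, cameraPR). The chemokine receptor gene Ccr8 went from 4 and 6 reads to 324 and 110 and Itga1, the collagen-binding integrin of resident T cells, from 49 and 21 to 729 and 108. The tetraspanin gene Cd9 went from 1139 and 697 reads to 180 and 143, and Itgae, the CD103 integrin, fell by 1.78 on the log2 scale in the authors' deposited table. Of 30 interferon-stimulated genes 3 rose and 8 fell, with 3 and 9 when adjusted over the list alone (adjusted p of the list 0.0772, cameraPR). Mx1 and Ifi44 went from 96 and 66 reads to 646 and 219 and from 37 and 17 to 237 and 115, while Isg20 went from 617 and 276 to 145 and 129 and Rtp4 fell by 1.54 on the log2 scale in the authors' deposited table. Ifi204 was the other member that rose. Among 26 glycolysis and lipid metabolism genes, 2 rose and 3 fell, as when adjusted over the list alone (adjusted p of the list 0.405, cameraPR). The cholesterol synthesis gene Sqle went from 1183 and 565 reads to 193 and 217, and the glycolytic gene Pkm also fell. Cpt1a, of fatty acid oxidation, and Fasn, of fatty acid synthesis, rose 2.53-fold and 2.92-fold in the authors' deposited table.

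Among imprinted, germline and developmental genes, few members were changed. Of 36 imprinted genes 17 were tested, 4 rose and 0 fell (5 and 1 adjusted over the list alone; adjusted p of the list 0.125, cameraPR, and 0.00148 with log2 fold change as the statistic). Ndn, expressed from the paternal copy in other tissues, had 0 reads in both WT libraries and 46 in each cTKO library, at least 31.7-fold higher. Sgce had 1 and 0 reads in WT and 58 and 65 in cTKO. Igf2r rose 3.05-fold in the authors' deposited table, and Peg13, which did not pass in limma on recovered reads without a sex covariate (adjusted p 0.107) and passed with it (0.0241), had 240 and 174 reads in WT and 1053 and 238 in cTKO. Of 31 germline genes 8 were tested and 1 rose, as when adjusted over the list alone (adjusted p of the list 0.227, cameraPR); this was Syce1, with 18 and 61 reads in WT and 107 and 266 in cTKO (limma on recovered reads, adjusted p 0.0907, and 0.000459 with a sex covariate; log2 fold change 1.27 to 3.45 with 1 library left out). Of 49 developmental transcription factors 3 were tested, with 1 higher and 1 lower also when adjusted over the list alone (adjusted p of the list 0.875, cameraPR). Gata6 had 3 and 2 reads in WT and 80 and 107 in cTKO, while Hoxa7 had 37 and 32 in WT and 1 and 0 in cTKO. Among 41 chromatin modifier genes 3 rose and 1 fell, as when adjusted over the list alone (adjusted p of the list 0.719, cameraPR). The higher genes were Phf19, of Polycomb complex 2, with 41 and 26 reads against 199 and 71, the H3K36 methyltransferase Nsd2, with 220 and 116 against 886 and 182, and Tet3, with 450 and 599 against 2026 and 656. Neither Nsd2 nor Tet3 passed in limma on recovered reads (adjusted p 0.125 and 0.101), and both passed with a sex covariate (0.0179 and 0.0439). The fit with a sex covariate leaves 1 residual degree of freedom, and that covariate cannot be told apart from library size. Without the larger cTKO library the log2 fold changes of Nsd2 and Tet3, with no sex covariate, were 0.53 and 0.69. Cbx1, a heterochromatin protein gene, went from 979 and 609 reads to 421 and 343, and its call was lost when fold changes were re-centred.

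Except where limma is named, p-values of genes are those of the authors' deposited table, and all list calls rest on a preset correlation of 0.01 between genes. With the correlation estimated from 2 libraries per genotype, 0 of 23 lists passed, and 0 had an unadjusted p under 0.05. That outcome does not measure correlation alone, since camera then rests on the few residual degrees of freedom of 4 libraries. The T cell receptor activation list had an estimated correlation of 0.0084, below the preset one. Its p still rose from 0.0067 to 0.112 (camera). On the same recovered genes 6 of 23 lists passed with the preset correlation in camera, and the memory, naive and linker histone lists did not (adjusted p 0.214, 0.355 and 0.344). With cameraPR on the limma scores of these genes 7 lists passed, the memory list among them (adjusted p 0.0268), so the call of that list depends on the test. When 8961 genes were fitted again by limma on recovered reads, 908 were higher and 194 lower at an adjusted p under 0.05, and 778 and 179 of these had the same call in the authors' deposited table. Leaving out any 1 of the 4 libraries moved both counts by more than 1.5 times, to between 209 and 356 higher and between 1 and 25 lower genes, with the lowest numbers without the larger cTKO library (509 lower at an unadjusted p under 0.05). Without the larger cTKO library none of the 9 lists was called on recovered reads, effector genes included (adjusted p 0.0506, cameraPR). Without the smaller cTKO library effector genes were the only one of the 9 still called (adjusted p 0.0437), and natural killer, B cell and memory genes were not (0.0748, 0.336 and 0.896). The sign of the fold change stayed that of the authors' table for all 1280 changed genes in this fit, whichever library was left out, which the choice of these genes by a comparison of the same libraries makes likely.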

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

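The tests in this part were chosen after the results were seen.

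Genes that carry no adjusted p in the authors' table, and so enter no comparison, had reads in cTKO libraries more often than in WT libraries. Among them, 546 genes had 0 reads in both WT libraries and reads in both cTKO libraries, while 69 genes showed the reverse. The larger cTKO library raises the first count, since it had reads in 3432 of 9951 genes silent in WT, against 237 of 6640 genes silent in cTKO for the larger WT library, so the 546 genes are not counted as a separate difference between genotypes. Over all genes with a mean under 1000, 9951 were silent in both WT libraries, and 100 of these had at least 10 reads in each cTKO library. In the other direction, 6640 genes were silent in both cTKO libraries and 4 had at least 10 reads in each WT library.

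Much of this signal lay in the larger cTKO library. Of 8946 genes at 0 in the other 3 libraries, 2678 had reads there (29.9%, 6920 reads), against 159 of 6427 for the larger WT, 135 of 6403 for the smaller WT and 251 of 6519 for the smaller cTKO library. The largest count among the 2678 genes was 38 reads. Genes of olfactory, vomeronasal and trace amine receptors, which are not expected in lymphocytes, took part: 247 of 1395 silent elsewhere had reads (17.7%), against 0.606%, 0.174% and 0.606% in the larger WT, smaller WT and smaller cTKO library. They took part less than other genes silent elsewhere, with 94.3 against 324 reads per megabase of exon in the larger cTKO library. These densities were 2.66 against 23.3 in the larger WT, 0.729 against 18.5 in the smaller WT and 2.90 against 37.6 in the smaller cTKO library. The tables argue against 3 single causes. Library size is not enough, since the larger WT library has nearly the same size factor and the larger cTKO library had 11.4 times as many genes with 1 read here and 0 elsewhere. Evenly spread genomic DNA would give X and autosomes like densities, and the density in reads per megabase of exon was 2.22 times as high on X (95% bootstrap interval over genes 1.76 to 2.72). This ratio was 1.48 (0.466 to 2.84) in the larger WT, 0.686 (0 to 1.70) in the smaller WT and 1.68 (0.696 to 2.89) in the smaller cTKO library. The first and last of these wide intervals include 2.22, so the X excess may not be particular to the larger cTKO library. A loss of H1 that acts alike in both animals would give the smaller cTKO library reads in about as many genes as the larger one thinned to its size, and among genes silent in both WT libraries it had 0.346 times that number (interval 0.327 to 0.366). That measure replaced the first one tried, the ratio of summed reads per size factor, which was 0.474 (0.426 to 0.524) and so did not exclude the limit of 0.5 set for it. Both lie below 1, the value for like action, while the WT pair gave an interval of 0.942 to 1.28 for the thinned genes and 1.04 to 1.63 for summed reads. A mixture of genomic DNA with low transcription, or an effect of H1 loss that differs between animals or sexes, may remain, and with 1 library of this kind the values cannot separate them; the intervals cover genes, not animals.

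The effector and natural killer receptor genes that rose could come from another make-up of the sorted cells. Natural killer cells in the CD8 gate would bring their abundant transcripts together, but Fcer1g had a log2 fold change of -2.70 in the authors' deposited table (2 SE on either side: -4.26 to -1.13). Ncr1 had 22 reads in the larger and 1 in the smaller cTKO library where Klrb1c had 1606 and 881. Against few WT reads, Ncr1 was higher in the larger libraries, as Klrb1c was, and only the smaller ones went the other way. Ncr1 thus gives no clear answer. Fcer1g lies in a part of chromosome 1 with many lower genes, which weakens the case against natural killer cells. A smaller share of naive cells is open: the naive list had a median log2 fold change of -0.51 in the authors' deposited table, and a table of sorted bulk cells cannot tell fewer naive cells from lower expression in each cell. A change of these genes within CD8 T cells by loss of H1 also stays open, as untested.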

How the results depend on the processing

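Of the alternatives in this part, the fits on recovered reads were added after the data were seen, and the rest were planned. With the authors' values, 1268 genes were higher and 468 lower. At an adjusted p under 0.01 these were 824 and 230, at 0.1 the lower genes were 776, and with a mean of at least 100 the higher genes were 739. The other planned settings kept both counts within 1.5 times (1161 to 1484 higher, 342 to 492 lower), and leaving out the sex-linked genes changed neither. The number of called lists lay between 7 and 11 against 9, and no list was called in the other direction. The lists of effector, memory, natural killer and B cell genes and of dissociation stress were called under every planned setting at an adjusted p under 0.05, while the linker histone list was lost with log2 fold change as the statistic (where its direction was lower), a correlation of 0.05 and the rank-based test, cell cycle genes with 2 other ranking statistics, naive genes with signed -log10 p and T cell receptor activation genes with the rank-based test. Lists gained at an adjusted p under 0.05 were myeloid genes (4 settings), interferon-stimulated genes (no filter) and, with log2 fold change as the statistic, imprinted, germline and developmental genes. A minimum fold gives no list value. Of 95 named genes, 11 lost their call at an adjusted p under 0.01; across the filter, gene set and centring settings 0 turned direction and 4 lost their call (Gata3 and Car2 with no filter, Ccr7, Cbx1 and Car2 with re-centring); the cause was not tested.

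On recovered reads limma gave 908 higher and 194 lower genes and 7 called lists. A sex covariate, which leaves 1 residual degree of freedom and cannot be told apart from library size, gave 1325 higher and 311 lower genes. Pseudocounts of 0.5 and 5 stayed within 1.5 times. Leaving out 1 library gave 209 to 356 higher genes, 1 to 25 lower genes and 1 to 6 lists. Without the larger cTKO library the 1 list was imprinted genes, and all 7 lists were lost (effector and natural killer genes at an adjusted p of 0.0506). Without the smaller cTKO library 6 of the 7 were lost, and the 3 called were effector, imprinted and myeloid genes. The lone library is then assumed to vary like the other genotype, with 1 residual degree of freedom. With an estimated correlation 0 lists were called, which the few residual degrees of freedom of that test make likely whatever the correlation. Of 64 named genes with recovered reads 57 passed in limma and 62 with a sex covariate; all 64 kept their direction without any 1 library, as their selection makes likely, and 3 of them passed without the larger cTKO library.

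DESeq2 size factors and pseudocounts for the authors' own values were not run, since the table has no values per sample. Animals could not be paired, because WT and cTKO animals carry different numbers. Matching by sex entered only through the sex covariate on recovered reads. Depth limits genes with a mean of 10 to 50, whose median SE was 0.98 on the log2 scale against 0.31 from a mean of 2000.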

Other observations

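Tests of X-linked genes in this part were set before their results were seen, after the excess itself was noticed; the windows and single genes were chosen after their values were seen.

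Some genes with no WT reads had reads in both cTKO libraries. With 0 reads in both WT libraries, Slc35f3 had 118 and 105 reads in cTKO, Nov 135 and 74, Pard3b 154 and 59, Adamts9 162 and 53, Ncam1 154 and 47, Pclo, a presynaptic scaffold gene, 115 and 65, and Pcdh9, a protocadherin gene, 124 and 56. Slc35f3 was at least 76.8-fold and Adamts9 at least 74.1-fold higher against 3 reads over the WT libraries. Of 1268 higher genes, 124 had 0 reads in both WT libraries and 96 of these had at least 10 in each cTKO library.

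Some changed genes lay side by side. Of 932 tests of windows of 5 Mb, 3 passed a hypergeometric test after Benjamini-Hochberg adjustment. On chromosome 1 from 170000001 to 175000000, 13 of 56 tested genes were lower (adjusted p 6.39e-05), among them the Ifi200 genes Ifi213, Mndal, Ifi208, Ifi209 and Ifi205. Ifi205 had 21 and 24 reads in WT and 0 in both cTKO libraries, at least 14.5-fold lower, while Ifi203, Ifi214 and Aim2 in the same window did not pass, with log2 fold changes of -0.03, 0.10 and -0.35 in the authors' deposited table, and Ifi204 was higher. Reads of this family are uncertain because its members are close copies, and a strain difference between WT and cTKO animals in this region was not tested. On X from 135000001 to 140000000, 12 of 26 genes were higher (adjusted p 0.000891). Bex1 had 0 reads in both WT libraries and 76 and 108 in cTKO, Bex4 0 against 73 and 103, Tceal3 0 against 61 and 51, and Tceal8 3 and 2 against 135 and 154. On chromosome 7 from 30000001 to 35000000, 9 of 50 genes were lower (adjusted p 0.0201). Xist, which silences 1 X in females, had 479 reads in the larger WT and 4871 in the larger cTKO library, and 2 and 28 in the smaller ones.

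X-linked genes were higher in 69 of 448 cases (15.4%), against 9.58% of autosomal genes (Fisher's exact test, two-sided, p 0.00013, adjusted p 0.00519 over 40 tests of 20 chromosomes in both directions). The hypothesis that the larger, female cTKO library alone gives this excess was tested on the smaller libraries. Of genes with a mean of at least 10 over all 4 libraries, 25.6% of 285 on X were at least 2-fold higher in cTKO. On autosomes the share was 16.4% of 7457 (odds ratio 1.76, interval 1.32 to 2.32, Fisher's exact test, p 9.51e-05). For these genes an excess was thus also there between the smaller libraries, 1 per genotype. This interval and p cover genes, not animals, and take neighbouring genes as independent. In the larger libraries alone the shares of the same genes were 32.6% and 27.5% (Fisher's exact test, p 0.0684). Low expression did not account for it either, since redrawing the calls within deciles of mean count gave a median of 47 X-linked calls, and 69 or more with p 0.00042 (one-sided permutation test, 100000 draws). Without the Bex, Tceal, Arxes, Gprasp and Armcx families, in which reads may be shared between copies, the odds ratio kept an interval above 1 (1.11 to 1.99, Fisher's exact test, p 0.00628). This p was not adjusted for the choice of X among 40 tests. Among those, chromosome 18 had p 0.00512 for higher genes and an adjusted p of 0.102 (Fisher's exact test). The families are thus not excluded as what sets X apart from the other chromosomes. An effect of H1 loss on X-linked genes is a candidate explanation, found and tested on the same 4 libraries, and a difference between the X chromosomes of the WT and cTKO animals was not tested.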
